A study of Homo sapiens with 2 samples.

How the data were processed

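RNA was taken from BE(2)-C neuroblastoma cells after puromycin selection of stable transfectants, 1 library with the empty vector and 1 with the GATA2-AS1 vector. Per the labels' protocols, RNA was extracted with TRIzol, libraries were made with the Illumina TruSeq RNA kit, and 100 bp paired-end reads were made on an Illumina sequencer. Per the submitters' processing notes, TopHat2 2.0.9 and Bowtie2 2.0.6 and the build hg38 were named. Per the labels' design text, HTSeq 0.6.0 counted reads per gene. The annotation release, the strand setting and the step from counts to the values are not given in the sources used here.

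The deposited values are RPKM, reads scaled by exon length and library size. Each library lists the same 26462 Ensembl genes, and 0 of the values are 0. A gene with no reads in one of the libraries is therefore not analysed here, including any detected in the other library alone. The design fixed beforehand assumed counts. Because the values are RPKM, no count model was used, and the planned quantities were computed from read pairs recovered from the values.

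Recovery used union exon lengths from GENCODE release 29 (GRCh38), which gave a length for 26209 genes and none for 253. RPKM times length falls on multiples of a fixed step in each library. The most common low value was taken as a whole number of pairs, and its largest submultiple at least 40% as common as itself was taken as 1 pair. That share was chosen after the low values of the real and simulated libraries were seen. In the empty vector library 1587 genes lay at 1 pair, 1131 at 2 pairs and 171 at 0.5 pairs, and in the GATA2-AS1 library 1582, 1059 and 140. Over all genes, 83.3% and 83.2% of values were multiples of 0.5 pairs within 0.001. A single mate would count 0.5 pairs. The remaining values have finer fractions, which whole-read counting does not give, so how fractions arose is open. With a length of GENCODE release 29, 11038 of 12147 genes (90.9%) with at least 200 summed pairs and under 20000 per library had both values on a grid of 0.01 pairs. Another single length fitted for 1107 genes, whose pairs are thus approximate, and none fitted for 2. That grid was chosen after the values were seen. The unit of 1 pair sets the read minimum and the intervals but not the RPKM values.

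Libraries were scaled by a weighted trimmed mean of log2 ratios (30% of ratios and 5% of abundances trimmed at each end), which moved the log2 ratio by 0.0067. The log2 ratio used a prior of 0.5 pairs. Genes needed 100 pairs summed over both libraries. Intervals are exact conditional binomial (Clopper-Pearson) at 95% and cover counting error only. PCR copies are not independent molecules, and the spread between cultures is not in them. Among 1826 genes over 2000 pairs in each library, the robust SD of the log2 ratio was 0.079 against a median counting error of 0.034, so differences beyond counting error were common and their source cannot be read from 1 library per group.

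Genes named in the text come from a rule fixed before the data were examined. It takes GATA2-AS1, GATA2 and MYCN, the 10 highest and 10 lowest ratios among genes with a symbol that are not pseudogenes, the 5 largest gains and 5 largest losses in scaled read pairs past 1.5-fold, and up to 4 members of each of 43 gene lists with the largest absolute log2 ratio. The text names only part of the list members that the rule takes, and no rule was stated for that part. The other shuttle enzymes and the genes beside MYCN in the closing observations were chosen after their values were seen. Lists used members with at least 100 pairs, 20 expression bins and 10000 random lists, and a percentile needed 5 members. Alternatives changed the scaling, the read minimum, the prior, the size rule, the gene class, the list summary and the matching. Removal of a GC trend, matching on GC, the use of the 0.01 grid and the mean of the tricarboxylic acid cycle list without MDH2 were added after seeing the data.

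The functions were tested on simulated libraries of GATA2-AS1 against empty vector with 14297 measured genes, single mates included. The step was recovered, 96% of 50 genes set 2.5-fold higher and 100% of 50 genes set 4-fold higher passed 2-fold, 2 unchanged genes passed 2-fold, and 95.4% of unchanged genes had an interval that held 1. Of 200 random lists, 6.5% fell outside the central 95%. Both genes moved off the grid were found, with 0 others in a random sample of the simulated genes. Simulated genes held only whole pairs and single mates, so the others lay on the grid by construction. Values with finer fractions were not simulated, so this gives no rate of false calls for them. The recovery of the step had to be corrected first. An earlier form took the most common low value as 1 pair and misread simulated depth; the correction left the steps of the real libraries as they were.

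Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.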

Results

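The study compared 2 RNA-seq libraries labelled as BE(2)-C, a human neuroblastoma cell line derived from a bone marrow metastasis. One library came from cells that stably carried an empty vector and the other from cells that stably carried an expression vector for GATA2-AS1, a long non-coding RNA transcribed from the strand opposite to the transcription factor gene GATA2. Each group had 1 library, so every difference below has no replicate check, no p-value is given, and all ratios compare these 2 libraries and not the conditions. The deposited RPKM values corresponded to denominators of 18530828 read pairs in the empty vector library and 19221358 in the GATA2-AS1 library. In each library, the recovered pairs summed over the genes with a length came to slightly more than the denominator. The cause of this excess was not tested, and it may bear on the pairs behind the read minimum and the intervals. Ratios are given as GATA2-AS1 over empty vector, with exact conditional binomial 95% intervals that cover counting error only.

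The first question was whether the transfected RNA was higher in the library labelled for it. GATA2-AS1 (ENSG00000244300, chromosome 3 from 128489212 to 128502348 on the plus strand of hg38) stood at 4.75 RPKM in the empty vector library and at 1761 RPKM in the GATA2-AS1 library. It was 368-fold higher, with an interval of 321 to 426, from 201 read pairs against 77292. GATA2 (ENSG00000179348, chromosome 3 from 128479427 to 128493185 on the minus strand), a zinc finger transcription factor of the sympathoadrenal and blood lineages, was at 36.2 and 47.6 RPKM. It was 1.31-fold higher in the GATA2-AS1 library, with an interval of 1.25 to 1.37. The gene bodies of GATA2 and GATA2-AS1 overlap, while their annotated exons share 0 bases. The strand setting of the counting is not given in the sources used here, so reads of intronic or unannotated sequence in the overlap could not be assigned to a strand. Of the other neighbours of the locus at 3q21.3, ABTB1 was lower with a log2 ratio of -0.57, from 60 and 42 read pairs with an interval that holds 1, the replication helicase subunit MCM2 was 1.24-fold higher and the mitochondrial dehydrogenase ACAD9 was 1.23-fold higher. Of the 16 measured genes in the list of neighbours, which includes GATA2, 9 had ratios above 1 and 7 below. Their median log2 ratio was 0.03, within the range of matched random lists (percentile 77.8).

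The second question was which other genes differed between the libraries. Among 14264 genes with at least 100 read pairs summed over both libraries, 4 were at least 2-fold higher in the GATA2-AS1 library and 8 were at least 2-fold lower. At 1.5-fold these counts were 44 and 87, and 99.1% of the measured genes lay within 1.5-fold. Beside GATA2-AS1, the genes past 2-fold on the higher side were the stress-responsive long non-coding RNA LUCAT1 (2.10-fold, interval 1.45 to 3.08), VEPH1 (2.10-fold, interval 1.44 to 3.15) and FAM83G (2.07-fold, interval 1.37 to 3.23). These 3 genes had 34 to 43 read pairs in the empty vector library, so their intervals reached well below 2-fold. The next genes by ratio were the kinase gene CDKL2 (1.96-fold), the secreted ligand WNT16 (1.91-fold), TSTD1 (1.77-fold), the chemokine CXCL8 (1.75-fold), C10orf55 (1.70-fold) and ZNF808 (1.70-fold). PLAU, the urokinase-type plasminogen activator, was 1.58-fold higher (interval 1.42 to 1.76), from 10.1 to 16.03 RPKM. Of its 2950 exon bases, 916 are shared with C10orf55, which lies on the opposite strand. Whether reads of the shared part were counted for either gene is not given in the sources used here. The DNA replication factor GINS3 was 1.502-fold higher.

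On the lower side, the lowest ratios belonged to MDH2 and GOT2, the mitochondrial malate dehydrogenase and aspartate aminotransferase. MDH2 (ENSG00000146701, chromosome 7) was at 53.8 RPKM in the empty vector library and 9.46 RPKM in the GATA2-AS1 library, 5.71-fold lower with an interval of 5.26 to 6.22. GOT2 (ENSG00000125166, chromosome 16) was at 31.0 and 8.42 RPKM, 3.70-fold lower with an interval of 3.39 to 4.06. The values of both genes differed in form from those of the others. Of 12147 genes tested, these were the only 2 for which no single exon length from 100 to 50000 bases turned both deposited values into read counts on the grid that the other genes followed, so their read pairs and intervals are approximate. Next came the antisense RNA TMC3-AS1 (2.88-fold lower, interval 1.88 to 4.62), the receptor tyrosine kinase ERBB4 (2.39-fold, interval 1.60 to 3.70), SSC5D (2.17-fold, interval 1.83 to 2.60), MBD6 (2.09-fold, interval 1.82 to 2.41) and SATL1 (2.00-fold, interval 1.41 to 2.98). A processed pseudogene without a symbol made up the count of 8. PTPN23, a phosphatase of endosomal sorting, was 1.97-fold lower, FAM86B1 1.93-fold, the haem carrier HPX 1.85-fold and PRR36 1.65-fold.

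**Figure D1:**
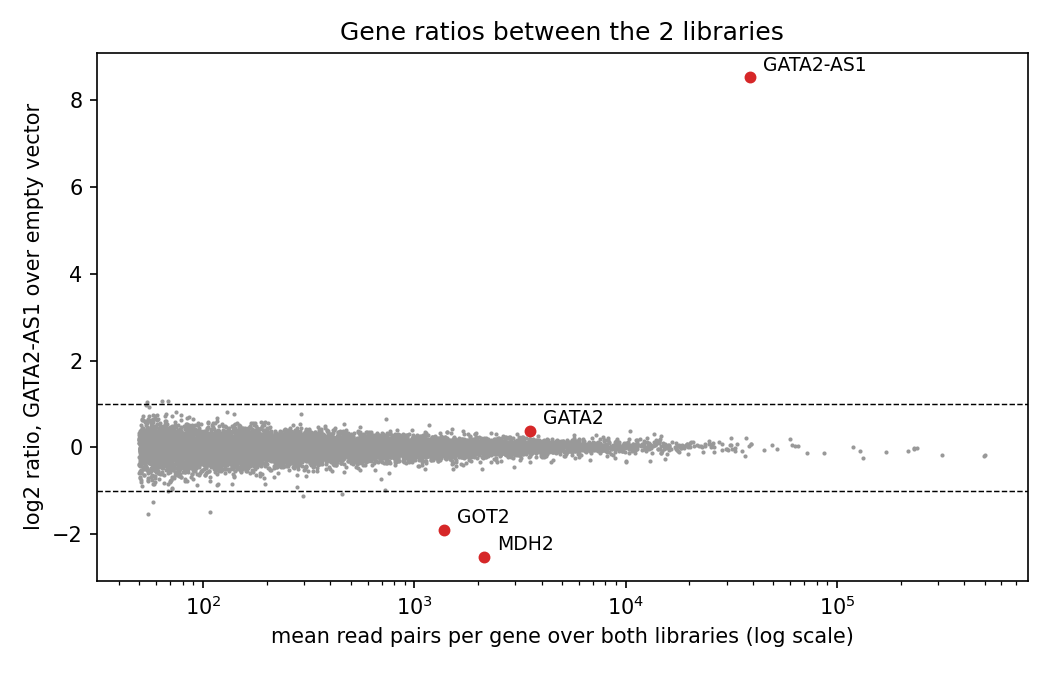
Log2 ratio of GATA2-AS1 over empty vector for each gene with at least 100 read pairs summed, against its mean read pairs over both libraries on a log scale, with 1 point per gene and dashed lines at 2-fold. GATA2-AS1 lies at a log2 ratio of 8.52, MDH2 at -2.51 and GOT2 at -1.89, apart from the band around 0 that holds GATA2 at 0.39.

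The third question was whether gene groups fixed before the data were examined stood apart. Each list's median log2 ratio was placed among 10000 random lists of the same size matched on mean expression, which describes these 2 libraries only. Of 36 lists with at least 5 measured members, 9 lay above the central 95% of their random lists, 6 lay below and 21 lay within, where 1.8 would be outside by chance. The random lists join unrelated genes, so genes that vary together pass this range more easily than the percentile states.

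Cell cycle genes were higher in the GATA2-AS1 library by small amounts. All 22 measured DNA replication genes had ratios above 1, with a median log2 ratio of 0.21 (percentile 100). CCNE1, the cyclin of S phase entry, was 1.34-fold higher, the replication factor CDC45 1.32-fold and the ribonucleotide reductase subunit RRM2 1.27-fold. Of 22 mitosis genes, 19 had ratios above 1, with a median of 0.13 (percentile 100), led by the mitotic kinase AURKB at 1.42-fold (interval 1.15 to 1.75) and the anaphase activator CDC20 at 1.29-fold. No member of either list reached 1.5-fold. The p53 targets went the other way, with 20 of 22 ratios below 1 and a median of -0.18 (percentile 0). CDKN1A, the p21 inhibitor of cyclin-dependent kinases, was 1.41-fold lower (interval 1.33 to 1.504), PHLDA3 was 1.33-fold lower, and the RNA-binding protein ZMAT3 was 1.22-fold lower. The cyclin-dependent kinase inhibitor and retinoblastoma family list lay within its range, with a median of 0.01 (percentile 59.9).

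Metabolic and translation lists had small positive medians. The cholesterol synthesis list had a median of 0.14 (percentile 100), with DHCR7, which makes cholesterol from its last precursor, at 1.27-fold higher. With a minimum of 1000 read pairs its median was 0.06 (percentile 95.1), within the range. The glycolysis median was 0.09 (percentile 99.8), with ALDOC at 1.37-fold and TPI1 at 1.25-fold higher. The cytosolic ribosomal protein median was 0.08 (percentile 100), and 33 of 36 members had ratios above 1. Nuclear-encoded oxidative phosphorylation genes had a median of 0.06 (percentile 98.2), but were within the range (percentile 94.0) when random lists were also matched on exon length. They were also within it by the mean (percentile 96.9) and with a GC trend removed (percentile 97). The mRNAs encoded by mitochondrial DNA lay on the other side, with 12 of 13 ratios below 1 and a median of -0.12 (percentile 0), led by MT-CO2 at 1.19-fold lower. Members as abundant as MT-CO2, at 141086 and 123682 read pairs, could be matched only loosely within an expression bin, which limits this percentile. The tricarboxylic acid cycle median was 0.01 (percentile 65.1), and MDH2 was its 1 member past 1.5-fold. The unfolded protein response median was 0.09 (percentile 99.9), with HERPUD1 at 1.19-fold higher. The integrated stress response median was 0.09 (percentile 98.6). This list was within the range by the mean (percentile 94.3) and with a minimum of 20 read pairs (percentile 97.0). The list of Polycomb and DNA methylation enzymes had a median of 0.07 (percentile 98.7), also within the range at that minimum (percentile 96.3). Fatty acid oxidation (percentile 93.7), hypoxia (percentile 86.1) and MYC target genes (percentile 96.8) lay within their ranges, although the MYC targets lay above when the mean replaced the median (percentile 97.54).

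The extracellular matrix, axon guidance, mesenchymal and Notch lists had negative medians. The extracellular matrix median was -0.09 (percentile 0), and HSPG2, the basement membrane proteoglycan perlecan, was 1.58-fold lower (interval 1.34 to 1.87). COL5A2 was 1.23-fold lower, whereas FN1, fibronectin, was 1.17-fold higher. The axon guidance median was -0.12 (percentile 0.01), with SEMA3E, a secreted semaphorin, 1.66-fold lower (interval 1.22 to 2.28) and SEMA3D 1.26-fold lower. The mesenchymal list had a median of -0.08 (percentile 0.77), with SNAI1 1.46-fold and AXL 1.28-fold lower, but was within the range with a minimum of 1000 read pairs (percentile 11.1). The Notch list had a median of -0.12 (percentile 1.1), and lay within the range when the mean replaced the median (percentile 6.45). In the TGF-beta and BMP list, which was within its range by its median (percentile 9.08) and below it by its mean (percentile 0.91), the BMP-responsive inhibitors of differentiation ID1 and ID3 were 1.83-fold (interval 1.35 to 2.51) and 1.79-fold (interval 1.397 to 2.32) lower, and the inhibitory SMAD7 was 1.33-fold lower. The matrix protease list had a positive median of 0.06, within its range (percentile 94.1), with PLAU its 1 member past 1.5-fold, and MMP13 1.49-fold lower.

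The adrenergic, catecholamine and neuronal lists lay within their ranges. The adrenergic transcription factor median was -0.03 (percentile 8.51), with TBX2 1.42-fold lower (interval 1.14 to 1.77), GATA3 1.36-fold lower (interval 1.29 to 1.43) and GATA2 higher, as given above. The catecholamine list had a median of 0.01 (percentile 63.0) and the neuronal differentiation list 0.04 (percentile 86.8). MYCN, known as amplified in BE(2)-C, had 31 and 24 read pairs, 0.64 and 0.48 RPKM. The identity of the line rests on the labels alone. The percentile was 92.0 for apoptosis regulators, 2.9 for heat shock, 9.8 for interferon response, 83.3 for immediate early genes, 57.1 for Wnt, 97.2 for integrins, 73.6 for angiogenic factors, 93.1 for HOX genes, 14.5 for haematopoietic partners of GATA factors and 43.1 for fibroblast and smooth muscle markers. Heat shock genes lay below their range by the mean (percentile 0.27) and with a GC trend removed (percentile 2.01), and integrins lay above when random lists were also matched on exon length (percentile 98.93) or GC content (percentile 97.77). Lists with fewer than 5 measured members had no percentile. Among those past the read minimum, ratios were above 1 for 1 of 4 neuropeptides, with NPY at 136 and 196 read pairs and ADM at 189.5 and 148. They were above 1 for 3 of 4 histones, with H2AC6 at 115 and 144 read pairs, for 2 of 4 Schwann markers, with S100B at 49 and 63, and for 1 of 4 epithelial markers, with MUC1 at 131 and 101. CD68 of the immune list was at 298.5 and 254 read pairs and EGFL7 of the endothelial list at 46 and 60. No erythroid gene reached the minimum.

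**Figure D2:**
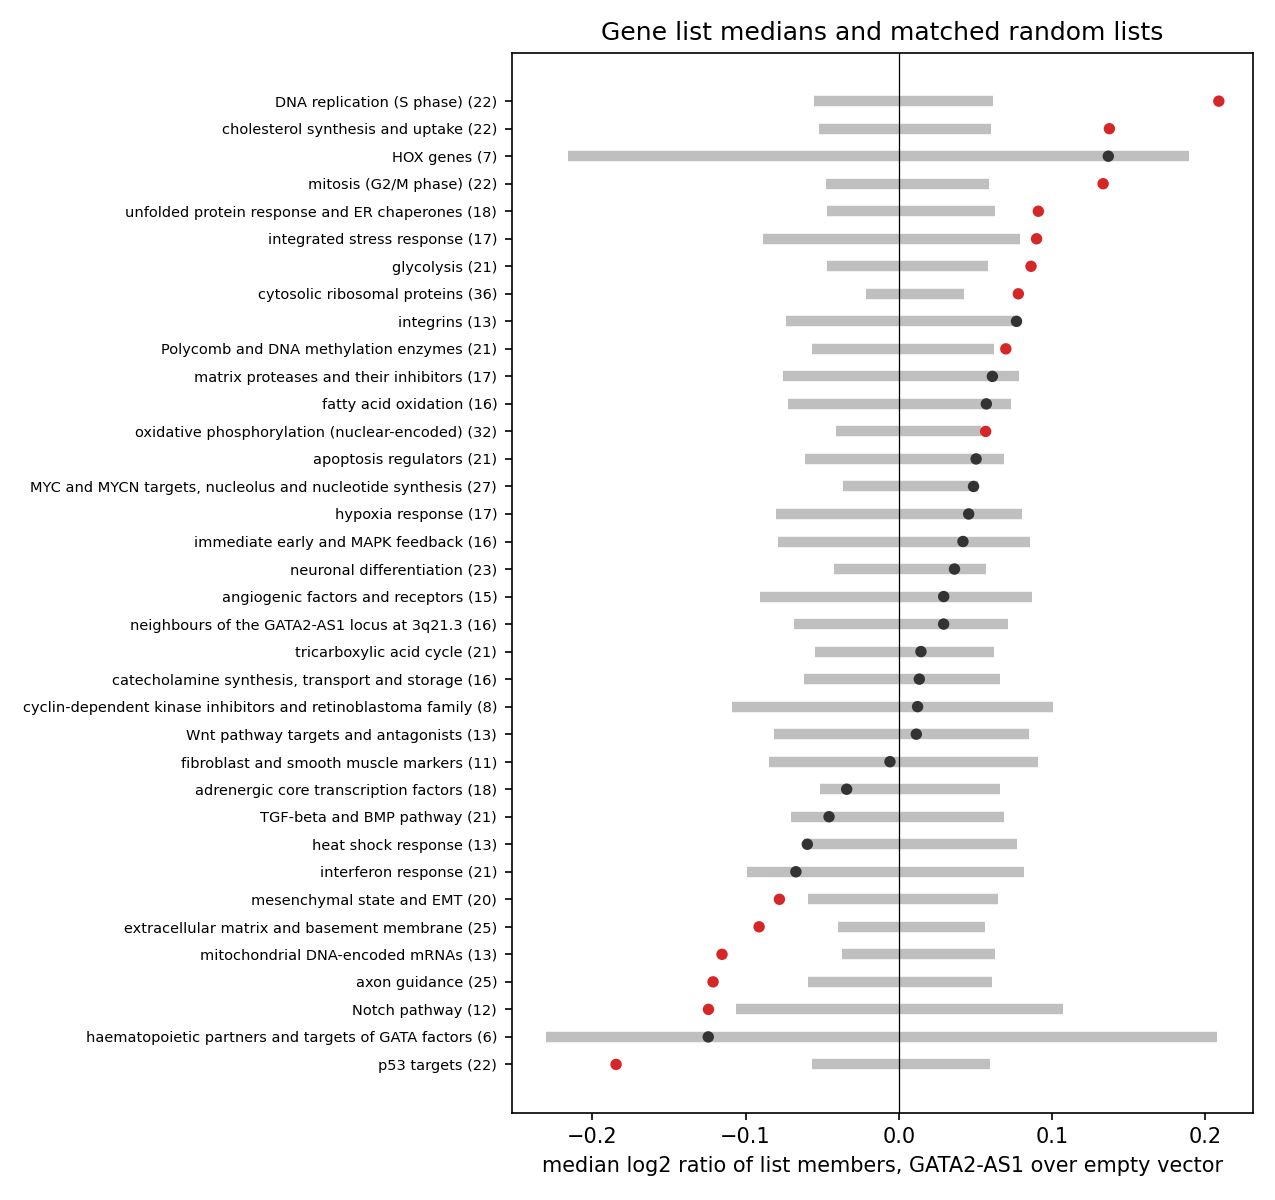
Median log2 ratio of GATA2-AS1 over empty vector for each gene list, with its number of measured members in parentheses (points, red where outside the range), and the central 95% of 10000 matched random lists (grey bars). DNA replication has the highest median at 0.21 and the p53 targets the lowest at -0.18.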

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

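GC trend removal, GC matching, both uses of the count grid and the mean without MDH2 were chosen after seeing the data. GATA2-AS1 and GATA2 stayed within their counting intervals under each scaling and prior tried, with log2 ratios of 8.49 to 8.54 and 0.39 to 0.40. The counts past 2-fold were 4 higher and 8 lower. They depended on the read minimum, with 1033 higher and 1067 lower at 1 pair, 112 and 150 at 20, and 1 and 2 at 1000. A prior of 5 left 1 higher. A whole interval past 2-fold left 1 higher and 3 lower. The 3 were MDH2 and GOT2, whose intervals are approximate, and the processed pseudogene without a symbol. A size of 1.5-fold gave 44 and 87, and 4-fold gave 1 and 1. Among protein-coding genes 2 were higher. Genes tested on the grid and fitting it gave 0 higher and 3 lower, since 3 higher and 3 lower genes had too few pairs for that test, GATA2-AS1 had too many, and MDH2 and GOT2 were tested and fitted no length. Leaving out only the genes that fitted no length gave 4 and 6. Of the 15 lists outside their random range, 9 stayed on the same side under all 9 alternatives. A change of scaling shifts list members and random genes alike, so the scaling alternatives could hardly change a percentile and are no check of it. The tricarboxylic acid cycle mean was -0.11 (percentile 0.31) against a median of 0.01, and without MDH2 the mean was 0.01 (percentile 64.0), so MDH2 made the shift. The cholesterol median at a minimum of 1000 was 0.058 against 0.14, and the cause was not tested. Of 183 recomputed log2 ratios of named genes, 1 left its counting interval, that of MT-CO2 at -0.23 under median-of-ratios scaling, and 0 with an interval that excluded 1 changed sign. The scalings moved every gene by nearly the same small amount, and the prior moved most named genes little. Most ratios, those of GATA2-AS1 and GATA2 included, could thus hardly leave their intervals, so this is a weak check. Few read pairs limit the precision of ratios near the minimum.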

Other observations

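The test of the count grid and of the level of MYCN were chosen after the values were seen. The tests of GC content, exon length and MYCN overlap were written down before their results.

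MDH2 and GOT2, 2 enzymes of the malate-aspartate shuttle, were 5.71-fold and 3.70-fold lower in the GATA2-AS1 library, while other members picked afterwards differed little: log2 ratios were 0.01 for MDH1, 0.12 for GOT1, -0.20 for SLC25A11, -0.05 for SLC25A12 and 0.12 for SLC25A13. MDH2 and GOT2 are also the 2 genes of 12147 for which no exon length put both deposited values on the count grid. Arbitrary values would match 0.007 and 0.04 lengths by chance, so finding no match is what arbitrary values would give. The other tested genes all fitted some length, unlike these 2. This is consistent with values of MDH2 and GOT2 made in another way than those of the other genes. How they were made cannot be read from the values, and a lower level of both mRNAs stays open. No pseudogene named for either gene is among those analysed here, so sharing of reads with pseudogenes was not tested.

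MYCN was low in both libraries, at 31 and 24 read pairs, although BE(2)-C is known as a line with amplified MYCN. Its neighbour DDX1 stood at 103 and 104 RPKM, NBAS at 6.29 and 6.06, and MYC at 8.22 and 9.43. Adrenergic genes were abundant, with HAND2 at 113 and 110 RPKM and SCG2 at 311 and 315. Loss of reads to an overlapping gene is argued against, since 96.2% of MYCN exon bases are free of other exons. MYCN lay at percentile 23.5 or lower among 15858 protein-coding genes. That restates its low level and does not tell cells without expression of an amplified MYCN from a value lost in the authors' processing, nor from cells of another line or subline than the labels name. All 3 stay open, and the last would change which cells every ratio here describes.

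More genes were at least 1.5-fold lower (87) than higher (44), and the lower genes had a median GC content of 52.2% and the higher genes 50.8%, against 47.5% for all measured genes. Across genes, the Spearman correlation of log2 ratio was -0.01 with GC content and -0.10 with exon length. After removal of a GC trend, 96.6% of the lower genes remained 1.5-fold lower, and after removal of an exon length trend 98.9% did. A steady trend with either therefore did not account for most of them. With correlations this near 0, removing a trend could change little, so other forms of bias are not excluded. Both the lower and the higher genes were GC-rich, and a spread of ratios that widens with GC content was not tested. No biological explanation was tested, and with 1 library per group the vector cannot be separated from differences between the 2 stable cell populations.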
